A study of Mus musculus with 8 samples.

How the data were processed

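Total RNA of sorted bone marrow haematopoietic stem cells from 8 mice was measured by sequencing, 4 wild type and 4 labelled Gata2; Mx1-Cre heterozygote, 1 library per mouse. Per the labels' protocols, 30 to 260 ng of RNA with an integrity number above 8 was depleted of ribosomal RNA, made into strand-specific libraries with 11 PCR cycles, pooled, and sequenced as paired reads of 75 bases. Reads were trimmed with Trim Galore and cutadapt and aligned with STAR 2.5.1b to GRCm38, per the submitters' processing notes. Fragments were counted per gene with featureCounts in reverse-stranded mode, requiring both ends to map and summing exons by gene identifier of GENCODE M17, per the file headers. The headers name featureCounts 1.6.2 and the submitters' processing notes name 1.5.1, a difference that was not resolved. The deposited values are raw fragment counts for 53715 genes, not normalized by the authors. Strand-specific counting separates antisense partners, but fragments that map to several places or overlap several genes on 1 strand were left out under the options in the headers, which lowers the counts of near-identical paralogs such as the haemoglobin and histone genes and some ribosomal protein genes with pseudogenes.

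Groups and replicate numbers were taken from the library descriptions. Symbols, biotypes and GC content came from a GENCODE annotation of the same build, in which 53620 identifiers had a symbol and 95 had none. Totals ran from 16750778 to 22861884 fragments, and 29748 genes had 0 counts in all 8 libraries. PCR copies were not marked by molecular identifiers, so floors of 3 counts cover counting error only. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom between any pair being 38.2, so all 8 were kept as separate samples. Whether mice of 1 genotype were littermates is not given in the sources used here.

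The comparison between genotypes used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with genotype as the group, counts were scaled by TMM (factors 0.946 to 1.08), and robust quasi-likelihood fits with genotype as the only term gave two-sided p-values, adjusted over 13992 genes by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are TMM-scaled. Log2 CPM values carry a prior count of 2. Fold changes are heterozygote label over wild type, with standard errors derived from the fitted change and its F statistic. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were alternatives. For a gene at 0 in a whole group the fold is a lower bound against 3 counts per library. The procedure was tested on simulated data, 5 simulations of 13992 genes drawn from the real means, dispersions and library sizes. edgeR called 25.6% of 2-fold and 56% of 4-fold genes and 17 unchanged genes over the 5 simulations, and DESeq2 called 39.8%, 68.4% and 226.

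Before the data were examined, 43 gene lists were fixed from textbook knowledge, of which 42 were tested and the sex-linked list served only to describe libraries. Lists with at least 5 tested members were tested with camera on log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over the lists, and again with an estimated correlation and with fry. In simulated data the megakaryocyte and platelet list, lowered by 0.5 on the log2 scale, was called in 5 of 5 simulations. None of the lists that share no gene with it was called, and lists that share a gene with it were not counted. Simulated genes vary independently, so that test does not cover correlation between genes. The genes named were also fixed by a rule. It took Gata2, then up to 12 genes past the threshold in each direction with a mean of at least 1 CPM and no overlap between groups, filled up to 5 per direction by smallest unadjusted p where fewer than 5 passed, then up to 4 members of each described list by unadjusted p, and the sort markers Kit, Ly6a, Slamf1 and Cd48. A few genes that the rule takes are not reported here.

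Alternatives fixed at the same time were other scalings, other tests, other filters on low counts, subsets of genes, the replicate number as a block, a term for sex read from Xist and Y-linked counts, other thresholds, and each of the 8 libraries left out. After the data were examined, removal of the trend of each library on GC content and gene length (loess), a filter at a mean of 16 CPM and a sex term in the list tests were added. Exact permutation tests ran over all 70 assignments of the 8 libraries. Exon-level counts were not used here, so the part of Gata2 that recombination removes was not measured separately.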

Results

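RNA was sequenced from haematopoietic stem cells of mouse bone marrow, sorted as lineage-negative, Sca-1-positive, Kit-positive cells that lacked CD48 and carried CD150. 4 libraries came from wild-type mice and 4 from mice labelled as Gata2 heterozygotes carrying Mx1-Cre, with 4 mice per genotype. Mx1-Cre is a recombinase transgene switched on by interferon, which the double-stranded RNA mimic pIpC induces, and all mice were 8 to 12 weeks old and received 6 doses of pIpC. The comparison asked how loss of 1 allele of Gata2, a zinc-finger transcription factor needed for the generation and maintenance of blood stem cells, alters the stem cell transcriptome. The library descriptions name Mx1-Cre for the heterozygotes only and do not say whether the wild-type mice carried it. If they did not, an effect of the transgene cannot be told apart from that of the Gata2 allele. Fragments assigned to genes numbered 22861884, 19037864, 22112022 and 22653131 in wild-type replicates 1 to 4, and 20022042, 16750778, 19059501 and 20042384 in the heterozygote-labelled replicates 1 to 4. Protein-coding genes took 97.0% to 97.6% of the counts, and between 16976 and 17906 genes were detected per library. Xist, the transcript of the inactive X chromosome, was present with no counts for 4 Y-linked genes in replicates 1 and 4 of both genotypes, and the reverse held in replicates 2 and 3, so both sexes were represented equally in each genotype.

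Gata2 transcripts were not lower in the libraries labelled heterozygote. The gene (ENSMUSG00000015053.14) lies on chromosome 6 from 88193891 to 88207032 on the plus strand of GRCm38, and its exons collected between 608 and 1011 fragments per library. Its level was 35.8 ± 7.65 CPM in wild-type cells and 44.8 ± 12.2 CPM in the heterozygote-labelled cells (SD, n = 4 each). The single libraries held 30.1, 45.3, 29.1 and 38.5 CPM in wild-type replicates 1 to 4 and 35.5, 61.9, 36.7 and 45.1 CPM in the heterozygote-labelled replicates 1 to 4. The log2 fold change was 0.33 (SE 0.23, adjusted p = 0.858 by edgeR), and an exact two-sided permutation test of log2 CPM gave p = 0.314, where 0.0286 is the smallest value that 70 assignments allow. The 95% interval of the fold change ran from 0.873 to 1.80 and excluded a halving of the total transcript. Counts were summed over all exons of the gene, so a transcript that had lost part of its exons would still have been counted, and the measurement does not show whether the recombined allele was present. Every direction given from here on follows the deposited labels, which the Gata2 level did not bear out.

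Of the 4 surface markers used in the sort, Ly6a was the one whose transcript levels did not overlap between the genotypes. Ly6a, which encodes Sca-1 and is itself induced by interferon, stood at 96.5 ± 17.6 CPM in wild-type cells and 139 ± 13.2 CPM in the heterozygote-labelled cells (SD, n = 4 each), and all 4 heterozygote-labelled libraries lay above all 4 wild-type libraries. Its log2 fold change of 0.53 (SE 0.15) had an unadjusted p of 0.0057 and an adjusted p of 0.850 by edgeR, so it did not pass. Slamf1, the gene of CD150, measured 34.0 ± 10.4 CPM and 24.0 ± 3.68 CPM in the same order, with a log2 fold change of -0.50 (SE 0.26). Kit differed by -0.15 (SE 0.18) and Cd48 by 0.06 (SE 0.23) on the log2 scale, and the sign of each turned in at least 1 alternative treatment of the data. Cd48 transcripts were detected at 23.5 ± 2.59 and 24.4 ± 6.41 CPM although cells with the protein had been excluded. None of these genes passed the threshold.

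**Figure D1:**
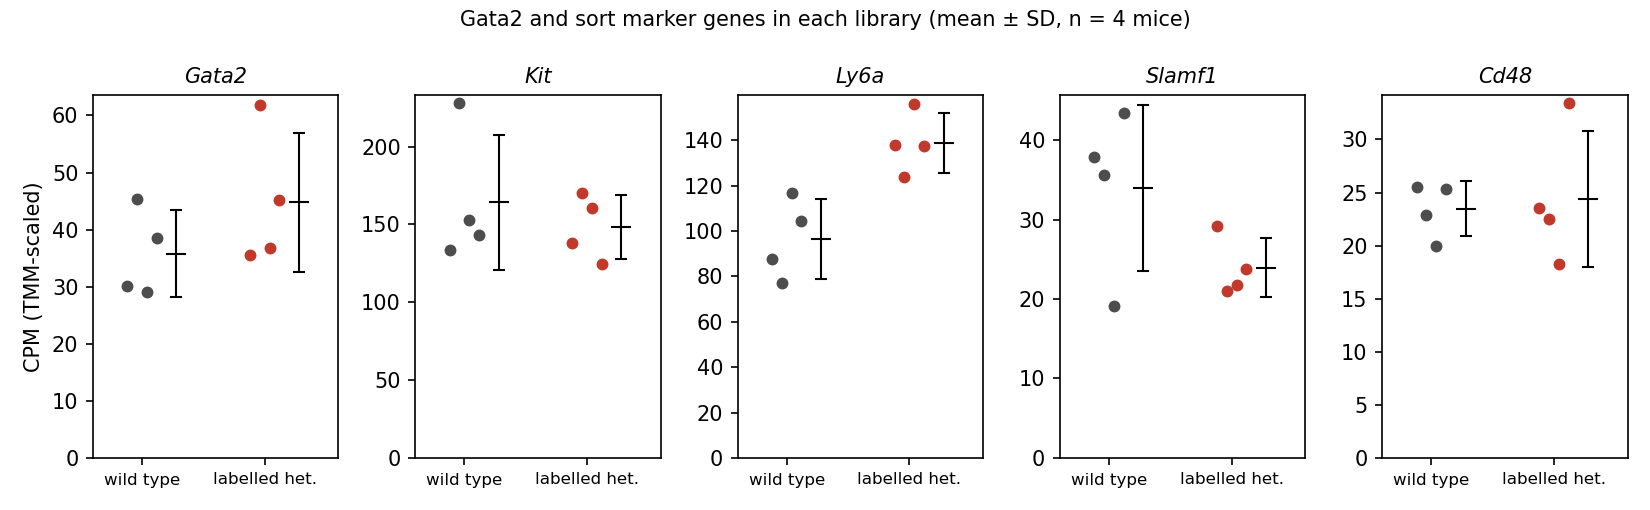
TMM-scaled CPM (vertical axes, each starting at 0) of Gata2 and 4 sort marker genes in each library, grey for wild type and red for the libraries labelled heterozygote, with the mean and SD of 4 mice beside the points. The Gata2 points overlap, with means of 35.8 and 44.8 CPM, while the Ly6a points separate completely.

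Across the transcriptome no gene passed the threshold in either direction. Of 13992 genes tested with edgeR, 0 reached an adjusted p of 0.05, the smallest being 0.834, and 792 genes (5.66%) had an unadjusted p under 0.05, of which 331 were higher and 461 lower in the heterozygote-labelled libraries. DESeq2 called 79 genes, 41 higher and 38 lower, and limma-voom with sample quality weights called 0, with 1461 genes at an unadjusted p under 0.05. Libraries of the same genotype were no more alike by the median than libraries of different genotypes. Correlations of log2 CPM across genes had a median of 0.907 within wild type (0.902 to 0.928), 0.905 within the heterozygote label (0.900 to 0.919) and 0.909 between them (0.892 to 0.921). The spread between mice was wide, with a biological coefficient of variation of 0.511, and in data simulated at that spread edgeR recovered 25.6% of genes changed 2-fold and 56% of genes changed 4-fold.

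The genes below had the smallest unadjusted p in each direction among genes with a mean of at least 1 CPM whose groups did not overlap. Predicted gene models and clones were left out. They are given as measured differences that did not pass with edgeR, where each gene below had an adjusted p of 0.834. Cald1 (ENSMUSG00000029761.16, chromosome 6 from 34598500 to 34775473), encoding the actin-binding protein caldesmon, had 0 counts in all 4 wild-type libraries and 2.73 ± 0.813 CPM in the heterozygote-labelled ones (SD, n = 4), which is at least 20-fold higher when the wild-type level is set at 3 counts per library. Gtf2a1, a subunit of the general transcription factor TFIIA, measured 233 ± 7.58 CPM in wild-type and 320 ± 20.1 CPM in the heterozygote-labelled libraries, a log2 difference of 0.46 (SE 0.09). Larp4b, an RNA-binding protein, differed by 0.74 (SE 0.16) and Gm2a, the lysosomal GM2 ganglioside activator, by 0.52 (SE 0.11). In the other direction, Klc1, a kinesin light chain, measured 15.5 ± 3.74 CPM in wild-type and 4.68 ± 1.52 CPM in the heterozygote-labelled libraries, a log2 difference of -1.73 (SE 0.33). Taf8, a TFIID subunit, differed by -0.97 (SE 0.20). Armh4, B3gnt3 and Cdyl2 averaged 2.80, 2.49 and 2.51 CPM in wild-type libraries and 0.0376, 0.0773 and 0.0579 CPM in the heterozygote-labelled ones, and 3 of the latter libraries held no Armh4 count. That the 4 against 4 libraries did not overlap was a condition for choosing these genes, so it is no evidence for them. 485 of the genes tested (3.47%) separated in this way, against 2.86% by chance. DESeq2 called each gene named here, but 5 of 35 splits of the libraries, the genotype split included, gave at least as many DESeq2 calls as the genotypes did.

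Transcripts of the megakaryocyte and platelet list were lower as a group in the heterozygote-labelled libraries. Of 22 tested members, 20 had a negative log2 fold change and the list median was -0.36 (camera adjusted p = 0.0033 with a preset inter-gene correlation of 0.01). The call did not hold with an estimated correlation (adjusted p = 0.485 with an estimated correlation), and without wild-type replicate 3 the median was -0.55. An exact permutation test of the list's mean deviation per library gave p = 0.0571 (adjusted p = 0.800 over the lists). Vwf, the carrier of clotting factor VIII and a marker of platelet-primed stem cells, measured 30.3 ± 5.48 CPM in wild-type and 16.6 ± 2.44 CPM in the heterozygote-labelled libraries (SD, n = 4 each), a log2 difference of -0.87 (SE 0.22, edgeR adjusted p = 0.850, DESeq2 adjusted p = 0.0142). Itga2b, the platelet integrin CD41, differed by -0.69 (SE 0.24) and Gp1ba, a subunit of the receptor for von Willebrand factor, by -0.81 (SE 0.39). The summed level of Ppbp and Tubb1, which are abundant in platelets, was 26.3 ± 6.57 CPM in wild-type and 20.8 ± 6.22 CPM in the heterozygote-labelled libraries. Singly they went opposite ways, Ppbp at -0.38 (SE 0.30) and Tubb1 at 0.95 (SE 1.43) on the log2 scale. GC-rich genes also took a larger share of the counts in 3 wild-type libraries. The correlation across genes of a library's deviation with GC content was 0.275, 0.338, -0.274 and 0.157 in wild-type replicates 1 to 4 and lay between -0.228 and -0.0892 in the heterozygote-labelled libraries.

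The erythroid list was lower as a group as well. 16 of its 19 tested members had a negative log2 fold change, with a median of -0.51 (camera adjusted p = 0.0151). Again the call did not hold with an estimated correlation (adjusted p = 0.773 with an estimated correlation). The exact permutation test of its mean deviation per library gave p = 0.143 (adjusted p = 0.800 over the lists). Car2, a carbonic anhydrase expressed in stem cells as well as red cells, measured 3266 ± 227 CPM in wild-type and 2658 ± 175 CPM in the heterozygote-labelled libraries (SD, n = 4 each), a log2 difference of -0.30 (SE 0.09). Aqp1, a water channel of red cells, differed by -0.89 (SE 0.35), and Blvrb, biliverdin reductase B, by -0.44 (SE 0.20). Slc25a37, the mitochondrial iron importer mitoferrin 1, went the other way, at 1.03 (SE 0.46). The call depended on single libraries, since without wild-type replicate 4 the median was -0.31 with an adjusted p of 0.197 and without heterozygote-labelled replicate 2 the median was -0.40 with an adjusted p of 0.107. Haemoglobin transcripts took at most 0.00388% of the counts in any library.

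Transcripts that mark multipotent progenitors, the cells immediately downstream of stem cells, were higher as a group. 13 of 15 tested members had a positive log2 fold change and the median was 0.27 (camera adjusted p = 0.0133), a call that did not hold with an estimated correlation (adjusted p = 0.485 with an estimated correlation). Without wild-type replicate 2 the median was 0.15, and the list still passed by camera at the preset correlation (adjusted p = 0.0219). The exact permutation test of its mean deviation per library gave p = 0.200 (adjusted p = 0.800 over the lists). Cd53, a leukocyte tetraspanin, measured 179 ± 49.4 CPM in wild-type and 306 ± 15.8 CPM in the heterozygote-labelled libraries, and Emb, the adhesion molecule embigin, 152 ± 19.7 and 235 ± 43.1 CPM (SD, n = 4 each). Their log2 differences were 0.78 (SE 0.19) and 0.63 (SE 0.15). By edgeR these 2 genes passed when p was adjusted over the list alone, which held for no member of any other list tested, and 0 passed over all genes. DESeq2 called both over all genes (adjusted p = 0.0430 for Cd53 and 0.0318 for Emb). Flt3, a cytokine receptor of lymphoid-primed progenitors, differed by 0.88 (SE 0.35) from a low level of 7.02 CPM, and Myc, a transcription factor of growth, by -0.50 (SE 0.22), against the direction of the list. Cd48, the member of the list whose protein was used in the sort, differed by only 0.06 (SE 0.23).

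Cytoplasmic ribosomal protein transcripts were slightly higher as a group, with 60 of 78 members positive and a median log2 fold change of 0.08 (camera adjusted p = 0.0133). Rpl5 differed by 0.25 (SE 0.13), Rpl35 by 0.31 (SE 0.17) and Rpl4 by 0.14 (SE 0.08), and wild-type replicate 2 lay below the other wild-type libraries in Rpl4. Members of this list vary together from mouse to mouse (estimated correlation 0.732), and the adjusted p was 0.930 with an estimated correlation. The exact permutation test of its mean deviation per library gave p = 0.486 (adjusted p = 0.869 over the lists). The call ended with a median of 0.02 when library size alone scaled the counts (adjusted p = 0.112), and it ended without wild-type replicate 2 (median 0.0097, adjusted p = 0.852), heterozygote-labelled replicate 3 (0.03, 0.324), wild-type replicate 1 (0.07, 0.0643) or heterozygote-labelled replicate 4 (0.07, 0.119). The median was 0.14 without wild-type replicate 3 and without heterozygote-labelled replicate 1, where the list passed.

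**Figure D2:**
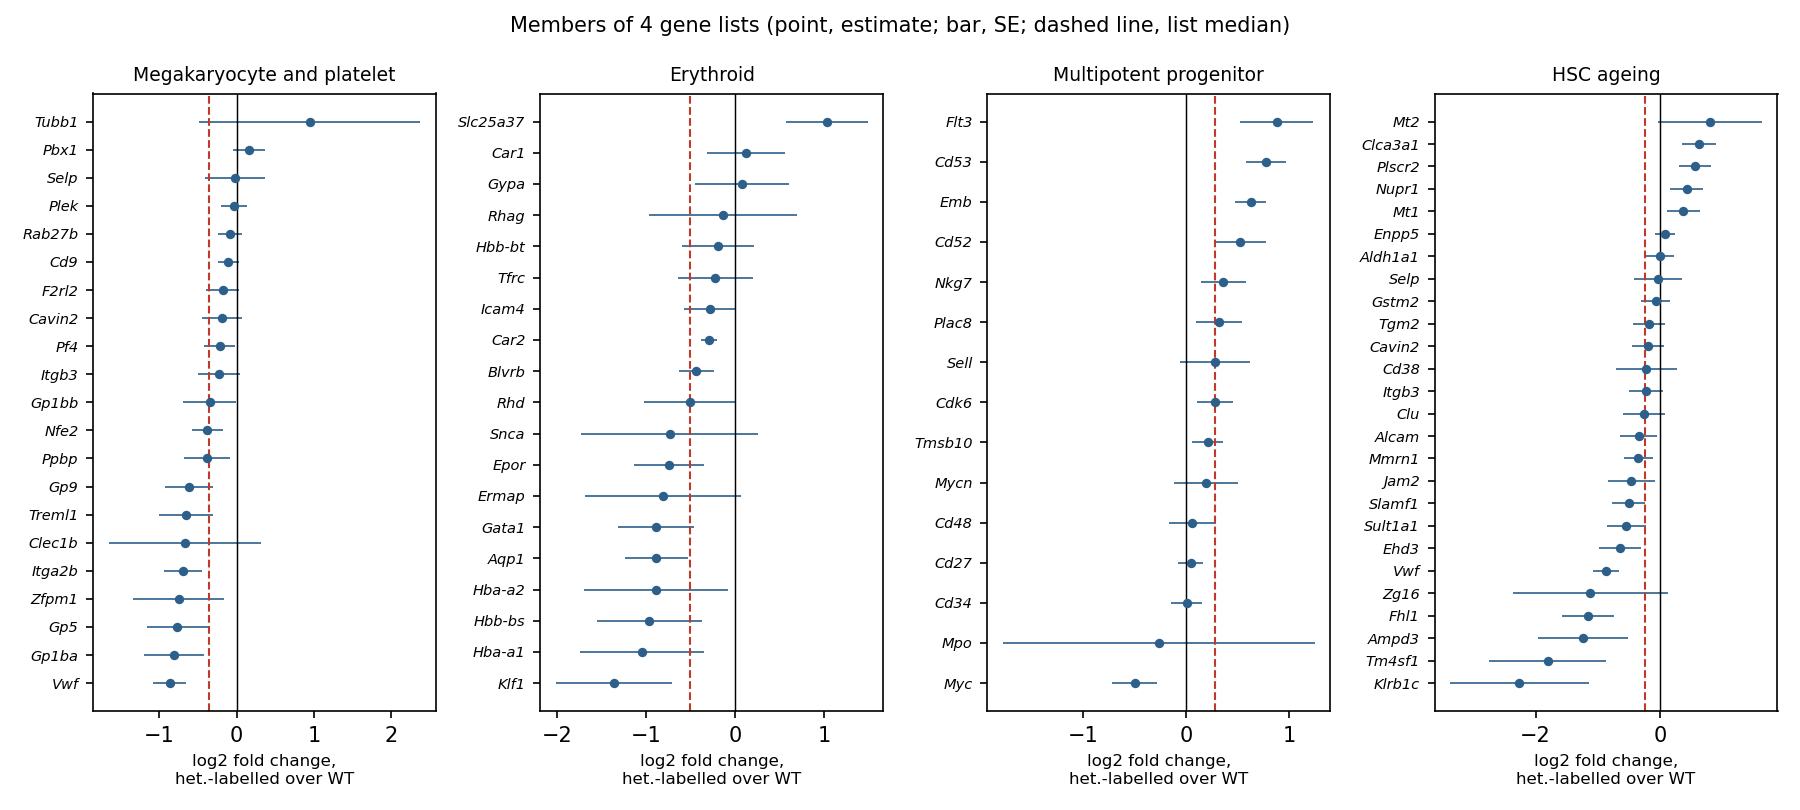
Log2 fold change of the heterozygote-labelled over the wild-type libraries (horizontal axes) for tested members of 4 gene lists, with the standard error as a bar and the median over all tested members as a dashed line. Most megakaryocyte and platelet genes, 16 of 19 erythroid genes and 19 of 26 genes of the ageing list lie below 0, and 13 of 15 multipotent progenitor genes lie above it.

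Stem cell identity genes showed no common direction. 11 of 27 members were higher and 16 lower, with a median log2 fold change of -0.08 (camera adjusted p = 0.859). Ifitm1, an interferon-inducible gene expressed in stem cells, was 741 ± 98.4 CPM in wild-type and 1007 ± 46.2 CPM in the heterozygote-labelled libraries, a log2 difference of 0.44 (SE 0.11). Tek, the receptor for angiopoietin, differed by -0.69 (SE 0.28) and Ctnnal1, encoding alpha-catulin, by -0.54 (SE 0.25). The list of haematopoietic transcription factors and cofactors had 10 of 16 members lower and a median of -0.21 (adjusted p = 0.205). Its members included Gata3 at -0.75 (SE 0.32), Gfi1b at -0.65 (SE 0.29), Lyl1 at -0.68 (SE 0.31) and Gata1 at -0.89 (SE 0.43). For Gata1, wild-type replicate 3 lay far below the other wild-type libraries, at a log2 CPM of 4.41 against 5.34 to 5.39. Genes described in earlier work as dependent on GATA2 had 13 of 19 members lower, with a median of -0.27 (adjusted p = 0.138, and adjusted p = 0.773 with an estimated correlation), among them Itga2b, Gfi1b and the mast cell carboxypeptidase Cpa3 at -0.72 (SE 0.29). The median of that list was -0.54 without heterozygote-labelled replicate 3 (adjusted p = 0.311) and -0.40 without wild-type replicate 2 (0.362), and it was -0.54 with a sex term (0.158). Genes described as raised in GATA2-deficient progenitors had 6 of 9 members higher and a median of 0.12 (adjusted p = 0.239), and the cytokine receptor subunit Csf2rb differed by 0.65 (SE 0.31).

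Mitotic genes were mostly lower without passing as a list. 24 of 30 members of the list for G2/M and mitosis had a negative log2 fold change, with a median of -0.14 (adjusted p = 0.138, and adjusted p = 0.773 with an estimated correlation). Left-out libraries moved this both ways, to a median of -0.07 without wild-type replicate 1 (adjusted p = 0.590) and -0.16 without wild-type replicate 2 (adjusted p = 0.0219), and with the trend on GC content and gene length removed the median was -0.08 (adjusted p = 0.137). Anln, the cytokinesis protein anillin, measured 37.1 ± 7.90 and 16.02 ± 7.32 CPM in wild-type and heterozygote-labelled libraries, a log2 difference of -1.21 (SE 0.34), and the 2 sets of libraries did not overlap. The mitotic kinesin Kif11 differed by -0.56 (SE 0.20), the spindle checkpoint kinase Bub1b by -0.77 (SE 0.33) and the kinetochore component Ndc80 by -0.53 (SE 0.25). Among genes of DNA replication 22 of 33 were lower (median -0.18, adjusted p = 0.278), with the helicase subunit Mcm5 at -0.42 (SE 0.17). DNA repair genes had 29 of 44 members lower (median -0.12, adjusted p = 0.326), with Rpa1 at -0.63 (SE 0.21), Lig1 at -0.48 (SE 0.19), Rad54l at -0.55 (SE 0.23) and Xrcc2 at -0.93 (SE 0.40). Quiescence genes had 13 of 22 members higher (median 0.13, adjusted p = 0.567), and the transcription factor Foxo3, a restraint on stem cell cycling, differed by 0.52 (SE 0.19).

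Glycolysis and oxidative phosphorylation genes lay on opposite sides of 0, and none of these lists passed by camera at the preset correlation with all 8 libraries. 16 of 22 glycolysis genes were lower (median -0.20, adjusted p = 0.161), with the pyruvate kinase gene Pkm at -0.74 (SE 0.27), the lactate dehydrogenase gene Ldha at -0.33 (SE 0.14), the enolase gene Eno1 at -0.40 (SE 0.18) and the glucose transporter gene Slc2a3 at -0.59 (SE 0.27). 45 of 60 nuclear genes of oxidative phosphorylation were higher (median 0.10, adjusted p = 0.0904), as were 9 of 10 mitochondrially encoded genes (median 0.26, adjusted p = 0.138). Among the nuclear genes the cytochrome c1 gene Cyc1 differed by -0.28 (SE 0.12), with libraries that did not overlap, and was the only member at an unadjusted p under 0.05. The ATP synthase subunit gene Atp5d differed by -0.47 (SE 0.26), also against the direction of the list, and Cox7b and Ndufa5, subunits of complexes IV and I, by 0.34 (SE 0.19) and 0.23 (SE 0.13). The nuclear median was 0.04 when library size alone scaled the counts (adjusted p = 0.180). Part of this contrast went with the trend on GC content and gene length. After its removal the median was -0.06 for glycolysis and 0.11 for the mitochondrially encoded genes (adjusted p = 0.727 and 0.702), while that of the nuclear genes was 0.08 (adjusted p = 0.0839). Single libraries moved these lists both ways. Without wild-type replicate 3 all 3 lists passed (adjusted p = 0.0325, 0.0446 and 0.00196 in the same order), with medians of -0.32, 0.37 and 0.21. The mitochondrially encoded and the nuclear list passed without wild-type replicate 4 (0.00374 and 0.0214), with medians of 0.51 and 0.13. The nuclear list passed without heterozygote-labelled replicate 1 (median 0.15, adjusted p = 0.0147) and with ranks in camera (0.0281). The medians shrank to -0.12 for glycolysis and 0.10 for the mitochondrially encoded genes without wild-type replicate 1 (adjusted p = 0.409 and 0.597, and 0.06 for the nuclear genes with 0.304), to 0.02 for the nuclear genes and 0.14 for the mitochondrially encoded genes without wild-type replicate 2 (0.821 and 0.458) and to 0.08 for the mitochondrially encoded genes without heterozygote-labelled replicate 4 (0.296). With all 8 libraries the adjusted p was 0.773 for glycolysis and the mitochondrially encoded genes and 0.930 for the nuclear genes with an estimated correlation. Whether the lists differed from each other was not tested. Mitochondrial transcripts took 0.880% to 2.08% of counts in wild-type and 1.31% to 2.28% in heterozygote-labelled libraries.

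Interferon response genes, of interest because pIpC acts through interferon, were balanced, with 23 of 40 higher and a median of 0.04 (adjusted p = 0.507) whose sign turned when library size alone scaled the counts. Rtp4 differed by 0.51 (SE 0.16) and Ifi44 by 0.45 (SE 0.19), both interferon-induced genes, while Irf1, an interferon regulatory factor, differed by -0.59 (SE 0.21). Apoptosis regulators went both ways. 14 of 23 were lower, with a median of -0.16 and a mean of -0.14, whereas camera placed the list on the higher side (adjusted p = 0.935). The caspase genes Casp8 and Casp6 and the apoptosome gene Apaf1 differed by 0.30 (SE 0.10), 0.33 (SE 0.12) and 0.70 (SE 0.25), with wild-type replicate 2 low for Casp6, and the anti-apoptotic Bcl2l1 by -1.64 (SE 0.60).

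Markers of other marrow cells gave no list that passed. The adjusted p was 0.518 for mast cells and basophils, 0.935 for granulocytes and monocytes, 0.983 for macrophages, 0.377 for B and plasma cells, 0.935 for T and NK cells and 0.507 for stromal and endothelial cells. The count filter kept 20 of 25 granulocyte and monocyte markers and 10 of 18 macrophage markers, but only 7 of 16 for mast cells and basophils, 7 of 20 for B and plasma cells, 6 of 20 for T and NK cells and 7 of 21 for stroma and endothelium. The vesicular monoamine transporter Slc18a2, a mast cell gene, differed by -0.47 (SE 0.14), the NK receptor Klrb1c by -2.26 (SE 1.12) from 4.97 CPM, and the collagen gene Col1a2 by -2.54 (SE 0.99) from 5.84 CPM. Cd79b, a component of the B cell receptor, was at 119 ± 11.6 and 113 ± 10.5 CPM in wild-type and heterozygote-labelled libraries (SD, n = 4 each). Lymphoid priming genes had 8 of 11 members higher (median 0.14, adjusted p = 0.243).

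Of 42 lists tested, 38 did not pass, with adjusted p from 0.0904 to 0.983. The median and the direction of the test differed in sign for the Notch list (median -0.24), the TGF-beta and BMP list (-0.01), the NF-kB list (0.0088) and the list of Hox genes and cofactors (-0.0062), and the median and the mean differed for the T and NK cell list (0.13 and -0.28) and the endoplasmic reticulum stress list (-0.07 and 0.0019). The remaining lists, covering niche adhesion, Wnt, cytokine receptors, histones, p53 targets, ribosome biogenesis, autophagy, antigen presentation, immediate early genes, epigenetic regulators, oxidative stress and the sort markers, had medians between -0.28 and 0.26.

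**Figure D3:**
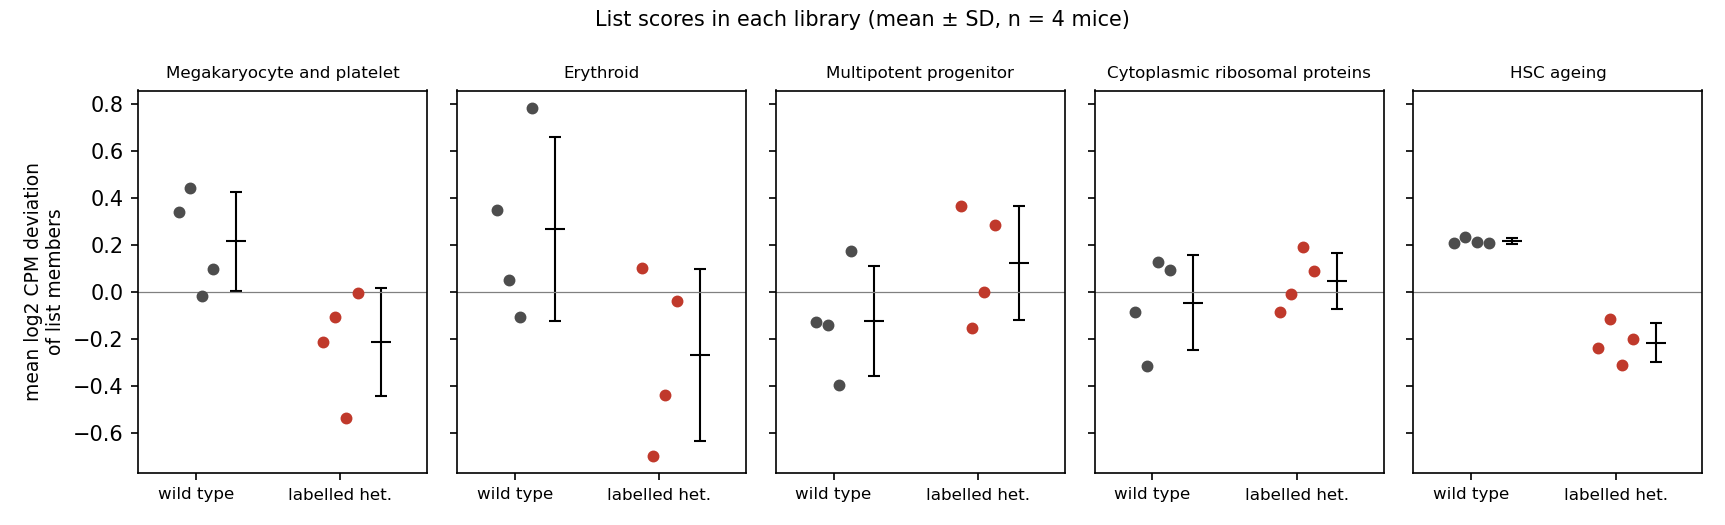
Mean deviation of log2 CPM from the 8-library mean over the tested members of 5 gene lists (vertical axis) in each library, grey for wild type and red for the libraries labelled heterozygote, with the mean and SD of 4 mice. The ageing list separates the genotypes, with wild-type scores from 0.209 to 0.234 and heterozygote-labelled scores from -0.310 to -0.114. The scores of every other list drawn overlap between the genotypes.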

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

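The outlying libraries below were found by a fixed rule applied to every gene named, 7 library measures and 42 list scores. In a group of 4, a library was picked out when its gap to the nearest other library as a share of the group's range exceeded Dixon's 95% critical value, and the ratio given is that share. Of 236 groups tested 10 were picked out, where chance gives about 11.8, so no excess over chance was seen and no explanation was weighed for them.

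Among named genes, wild-type replicate 3 had a Gata1 log2 CPM of 4.41 against 5.34 to 5.39 in the others (ratio 0.944). Wild-type replicate 2 was low for Casp6 (6.52 against 6.79 to 6.85, ratio 0.831) and for Rpl4 (11.1 against 11.2, ratio 0.899). For Armh4 the only heterozygote-labelled library with any count was replicate 1, which gives a ratio of 1.

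Heterozygote-labelled replicate 4 had the highest mitochondrial share of its group, 2.28% against 1.31% to 1.45% (ratio 0.85), and a B and plasma cell list score of 1.16 against -0.956 to -0.812 (ratio 0.932). Wild-type replicate 2 had the lowest histone list score, -0.27 against 0.13 to 0.15 (ratio 0.952). The DNA repair list score was lowest in wild-type replicate 3, -0.176 against 0.118 to 0.151 (ratio 0.899), and highest in heterozygote-labelled replicate 2, 0.121 against -0.126 to -0.0986 (ratio 0.889). The score of the list of Hox genes and cofactors was lowest in wild-type replicate 3, -0.354 against 0.0771 to 0.105 (ratio 0.939).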

How the results depend on the processing

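No alternative of edgeR or limma-voom called a gene. edgeR called 0 genes under every scaling, filter, subset, threshold, fold minimum, sex term and left-out library tried (range 0 to 0 higher and 0 to 0 lower without each library), with the replicate block (0 genes, 946 at an unadjusted p under 0.05), with the trend on GC content and length removed, and with a mean of at least 16 CPM (6658 genes, smallest adjusted p 0.446). The last 2 and the sex term for lists were chosen after seeing the data. DESeq2 called 79 genes, 41 higher and 38 lower. Over the 5 simulations it also called 226 unchanged genes, against 17 by edgeR. At least as many calls came from 5 of 35 splits of the libraries, the genotype split included. Its calls are therefore no firm evidence of a genotype difference. Why it called more genes than edgeR in the real data was not tested further. The replicate numbers were not taken to pair the mice. Same-numbered mice shared a sex, but deviations of same-numbered libraries correlated at only 0.0293, -0.0072, 0.0889 and 0.0030, and replicates 1 and 3 but not 2 and 4 correlated best with their own number. Under the replicate block the Gata2 log2 fold change was 0.31, 4 lists were called and the erythroid median was -0.79.

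The Gata2 difference was positive and not past the threshold in all 22 alternatives, from 0.13 without heterozygote-labelled replicate 2 to 0.61 with the GC trend removed; the left-out libraries gave 0.13 to 0.47. Of 1483 combinations of 68 other named genes with an alternative, 1478 had the sign of the main value and 13 passed 0.05, all by DESeq2. The sign turned for Kit without wild-type replicate 2 (0.065; left-out libraries gave -0.227 to 0.065), and for Cd48 with library size only (-0.0094), with the GC trend removed (-0.152), without wild-type replicate 3 (-0.0107) and without heterozygote-labelled replicate 4 (-0.132; left-out libraries gave -0.132 to 0.174). The cause was not tested.

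The count of 4 lists became 0 with an estimated correlation and 1 with fry, which found the ageing list only, was 5 with ranks in camera, where the nuclear oxidative phosphorylation list passed as well, and ranged from 3 to 8 over the left-out libraries, with 8 without wild-type replicate 3. The megakaryocyte and multipotent progenitor lists were called in each of the 8, with medians of -0.553 to -0.274 and 0.15 to 0.315. The median of the stem cell identity list turned with the GC trend removed (0.0322) and without heterozygote-labelled replicate 3 (0.0013; left-out libraries gave -0.198 to 0.0013). That of the interferon list turned with library size only (-0.023), without wild-type replicate 3 (-0.0307) and without heterozygote-labelled replicate 2 (-0.0067; left-out libraries gave -0.0307 to 0.118). The list of GATA2-dependent genes passed at the preset correlation with a mean of at least 16 CPM (median -0.66, adjusted p = 0.0118) and without wild-type replicate 3 (adjusted p = 0.0440), and the mitotic list without wild-type replicate 2 (adjusted p = 0.0219), although its adjusted p was 0.590 without wild-type replicate 1 and 0.311 without heterozygote-labelled replicate 3. The level of a gene limits what could be called. In data simulated at this spread edgeR called 1 of 246 genes changed 2-fold with a mean below 16 CPM (0.407%, exact binomial 95% interval 0.0103% to 2.24%) and 127 of 254 at or above it (50%, 43.7% to 56.3%).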

Other observations

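The list of genes that rise in ageing stem cells had scores that separated the genotypes without overlap. 19 of 26 tested members had a negative log2 fold change, with a median of -0.24 (camera adjusted p = 0.105, fry adjusted p = 0.0403 for a common direction and 0.0175 for change in either direction, camera adjusted p = 0.485 with an estimated correlation). Without wild-type replicate 2 the median was -0.14 (camera adjusted p = 0.265). The mean deviation of the list was 0.209, 0.234, 0.214 and 0.209 in wild-type replicates 1 to 4 and -0.241, -0.114, -0.310 and -0.200 in the heterozygote-labelled replicates 1 to 4, a difference of -0.43 with SDs of 0.012 and 0.0818. The exact permutation p was 0.0286, the smallest that 70 assignments allow, and it was the only list of 42 to reach it, where chance gives about 1.2. The result did not pass adjustment over the 42 lists (adjusted p = 0.800). Once the trend on GC content and gene length was removed 3 lists reached 0.0286, the others being the megakaryocyte and the Wnt list. Vwf is a member of this list as well as of the megakaryocyte list. Without the 4 members shared with the megakaryocyte list the difference over 22 genes was -0.45 with the same exact p of 0.0286. Fhl1, a LIM domain protein, differed by -1.16 (SE 0.41), while Clca3a1 and Plscr2 differed by 0.63 (SE 0.27) and 0.56 (SE 0.26), against the direction of the list. Members changed unevenly, with a mean log2 fold change of -0.37 and an SD of 0.72 over the members. The most negative member, Klrb1c, differed by -2.26 (SE 1.12) from a low level of 4.97 CPM in wild-type libraries. The members that are lower include platelet and adhesion genes, and all of the mice were young.

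Of the tests that follow, those on Gata2, on the trend in GC content, on platelets and red cells, on sequencing depth and on the neighbourhood of Gata2 were chosen after the results were seen, and the splits of the libraries and the variance slope were fixed before.

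Other divisions of the 8 libraries gave results as large as the genotype did. For the edgeR count the comparison is void, because any of the 35 splits into 4 and 4 reaches the 0 genes of the real split. The highest of the others was 5, for the split by sex. For genes at an unadjusted p under 0.05 the real value of 792 was reached in 6 of 35 splits, with 1986 as the highest other, and for DESeq2 the real value of 79 was reached in 5 of 35, with 791 as the highest other. The 4 lists called by camera were reached in 10 of 35 splits, with a highest other value of 9. Each of these counts of splits includes the real split. Chance can therefore not be excluded for these 3 counts. The split with 791 DESeq2 calls sets wild-type replicates 1, 2 and 4 and heterozygote-labelled replicate 1 against the rest. It differs from the genotypes only by exchanging wild-type replicate 3 and heterozygote-labelled replicate 1, and it was picked after the counts were seen. It therefore cannot show whether the samples have a structure other than genotype, which was not tested. Exchanging wild-type replicate 3 with heterozygote-labelled replicate 4 instead gave 643 calls. Wild-type replicate 3 lay nearer to every heterozygote-labelled library than to any other wild-type library. Its chi-square per degree of freedom was 38.91 to 52.15 against the former and 63.9 to 108.1 against the latter. Wild-type replicates 1, 2 and 4 are also the libraries with the positive trend on GC content.

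Gata2 counts were not lower in the libraries labelled heterozygote, as loss of 1 allele might lead one to look for. Scaling between libraries does not account for this, since the lowest log2 difference over 4 scalings was 0.252 (SE 0.247). Removal of the trend on GC content and gene length moved the difference away from a loss, to 0.607 (SE 0.24). Swapped labels that hide a halving are argued against as well, because the lowest mean log2 CPM difference of any of the 70 assignments was -0.523 and a halving needs -1. What stays open, and was not tested, is that a recombined allele may still make a transcript counted over its remaining exons, that the other allele may be raised, or that recombination was incomplete.

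The megakaryocyte and erythroid lists were lower and the multipotent progenitor list higher in the heterozygote-labelled libraries by camera at the preset correlation, and all 3 calls were lost with an estimated correlation (adjusted p = 0.485, 0.773 and 0.485). After removal of the GC trend the largest camera adjusted p of the 3 lists was 0.0149 at the preset correlation. The medians were then -0.26, -0.41 and 0.28 in the same order, against -0.36, -0.51 and 0.27 before. The trend therefore went with part of the first 2 differences. It does not account for the whole pattern as called at the preset correlation. Platelets left in the wild-type libraries stay open, although the sort removed lineage-positive cells, since the largest gap in Ppbp plus Tubb1 between any wild-type and any heterozygote-labelled library was 21.7 CPM, and 19 other members, without Pf4, which stem cells express too, together exceeded the heterozygote-labelled level by 303 CPM with a 95% interval of -42.0 to 648 CPM, the largest part being Nfe2 at 489 against 377 CPM, singled out after its values were seen. Red cells stay open as well, since the largest haemoglobin gap was 25.6 CPM, an undercount where fragments that map to several places were dropped, against 59.3 CPM (-65.1 to 184) for 14 other members without Car2. Chance is not excluded either, as 10 of 35 splits, the real split included, called at least as many lists. Nor is a shift among kinds of stem cell within the sort gate excluded, a hypothesis that bulk counts could not test.

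Many genes had 0 counts in a library while the other libraries averaged a sizeable count. Summed over the 8 libraries, 1742 times a gene had 0 counts where the other 7 libraries averaged at least 20, from 148 in wild-type replicate 2 to 328 in heterozygote-labelled replicate 3. The other libraries could include zeros too, and a gene at 0 in several libraries could count more than once. Sequencing depth is excluded, since Poisson draws at these depths give 1.6e-05. Few starting molecules per gene may contribute, but the slope of log variance on log mean within groups was 1.5 (bootstrap SE 0.013) for genes with a mean of 10 to 300 counts, at the boundary set in advance, so few molecules and variation between mice cannot be told apart. Cald1 was not missing from a single library only. It was 1 of 4 genes with 0 counts in 1 genotype and at least 3 in every library of the other. That number of genes was reached in 16 of 35 splits, the real split included, with 8 as the highest other.

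A region carried along with the targeted allele was tested as a hypothesis around Gata2. Of 102 genes within 5 Mb, 8 (7.84%) had an unadjusted p under 0.05, against 5.64% of the 13890 other genes (one-sided Fisher exact p = 0.220), so the test could not decide.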
